A study of Arabidopsis thaliana with 9 samples.

How the data were processed

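The labels' protocols state laser dissection of shoot apical meristems, RNA extraction, RNA amplification and cDNA synthesis with random primers. The 9 libraries fall into 3 time points of 3 libraries by their titles. Per the labels, libraries A and B were whole-transcriptome shotgun libraries and library C a ready-to-run library, which makes 6 libraries of one kind and 3 of the other.

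The authors deposited a table of read counts per locus with 16 count columns. Per the file headers, 7 libraries had a column for read 1 and a column for read 2, and 2 libraries (LD0 A and LD3 A) had 1 column. Per the file headers, reads were matched with BLASTN 2.2.21 in 7 columns and BLASTN 2.2.13 in 9, and the versions cross the time points. The sequencer, the genome build, the filters on matches, the use of strand and the treatment of reads with several matches are not given in the sources used here, so no coordinates are given, and genes that overlap or have near-identical copies may share reads. In the deposited counts, 49.0% of cells were empty, 0 cells held a zero, and empty cells were read as 0 reads. The columns of a library were summed. Where a library has reads 1 and 2, a fragment can count in both columns, so summed counts overstate the number of fragments. The table holds 23338 loci, of which 23073 were matched by identifier in the RefSeq annotation of TAIR10.1, used for symbols only.

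The authors also deposited 3 tables of pairwise comparisons made with edgeR, per the submitters' processing notes, with a log2 fold change, a log2 concentration and an unadjusted p-value per locus. The edgeR version and the design are not given in the sources used here. The plan had assumed an adjusted p in these deposited tables. As they hold an unadjusted p-value, the Benjamini-Hochberg adjustment was computed here.

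Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test. Libraries were scaled by TMM factors, genes were kept by filterByExpr with a minimum count of 10, and the model held the time point and the library preparation as additive terms over all 9 libraries. This left 9300 genes, 5 residual degrees of freedom and a common biological coefficient of variation of 0.898. The median standard error of a log2 fold change was 1.30 for LD1 against LD0, 1.26 for LD3 against LD0 and 1.24 for LD3 against LD1. A joint test on both long-day coefficients asked for any change over the 3 time points. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The term for library preparation itself called 78 genes. CPM are the summed reads per 1000000 of the scaled library size, and means are given with the SD over 3 libraries. Ratios of pooled reads divide the reads of a gene, summed over a group, by all reads of that group, without TMM factors. The deepest library of a group therefore weighs most in them. They have exact 95% counting intervals, which treat the summed reads as independent, and the detection limit is 3 reads per library.

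Gene lists were fixed before the data were examined: 20 lists of floral promoters, floral repressors, floral organ identity, meristem maintenance, polarity, cell cycle, hormone, clock, sugar, stress and ribosomal genes, with markers of leaf mesophyll, vasculature, trichomes and stomata, and the epidermal layer. Lists with 2 or more tested members were tested, a rule chosen after the data were seen, which left 18. The test was camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. With the preset correlation 3 lists passed between LD1 and LD0, 6 between LD3 and LD0 and 1 between LD3 and LD1. Camera with an estimated correlation passed 0, 0 and 0 lists, and fry 0, 3 and 0. A list of seed storage and late-embryogenesis genes with 32 members and a list of pollen genes with 14 were added after high seed gene counts had been seen. SESA5, EM1, EM6, PAP85 and RAB18 of the seed list and SKS13 of the pollen list were known to be high before the lists were written.

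Genes named in the text were set by a rule fixed before the data were examined. It took up to 6 genes per direction with an adjusted p under 0.05, a mean of at least 20 reads and the same sign in each letter, up to 4 past the threshold per list, and 20 flowering and meristem genes whatever their result. The parts that need an adjusted p over all genes gave 0 genes. The 5 genes with the smallest p per comparison and list members that passed over their list alone were added after their values were seen.

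The gene test was tested on simulated counts for LD3 against LD0 over 9300 genes with 200 of them changed, in 10 simulations. Of genes changed 4-fold, 0.8% were called and 32.1% had an unadjusted p under 0.05. Of genes changed 16-fold, 13.1% were called and 79.0% had an unadjusted p under 0.05. Median recovered log2 changes were 1.99 and 3.94. Of unchanged genes, 4.49% had an unadjusted p under 0.05, but they made up 20.6% of the calls (36 of them beside 139 changed genes), more than the 5% aimed at. A list of 30 genes changed 4-fold was found in 10 of 10 simulations by camera and an unchanged list in 0 of 10. Genes were drawn independently there, so this does not test lists whose members vary together.

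Alternatives fixed before the data were examined were other scalings, no filter and a minimum count of 30, DESeq2 1.42.0, limma-voom with quality weights, edgeR's exact test, fits without the preparation term or with the replicate letters as a block, libraries A and B alone, and each of the 9 libraries left out in turn. Chosen after the data were seen were 1 count column per library, removal of ribosomal RNA and organelle loci, removal of the seed and pollen lists, and thinning of every library to 97153 reads.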

Results

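Transcript levels were measured in laser-dissected shoot apical meristems of Arabidopsis thaliana, accession Col-0. The shoot apical meristem is the group of dividing cells at the tip of the shoot that forms leaves and, after the floral transition, flowers. Plants stood in short days of 8 h light and 16 h darkness and then received 0, 1 or 3 long days of 16 h light and 8 h darkness, here named LD0, LD1 and LD3. The series asked how the transcriptome changes from the vegetative meristem to the transition meristem, before floral meristems form. Each of the 3 time points had 3 libraries, lettered A, B and C. Per the labels, A and B were whole-transcriptome shotgun libraries and C was a ready-to-run library, so each time point held 2 preparations. The labels do not say how many plants a library came from or whether the replicates were separate plant pools, so p-values measure only the spread between these libraries, which may be technical.

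Depth differed widely. The LD0 libraries A, B and C held 108753, 97153 and 2187205 reads assigned to loci, the LD1 libraries 124360, 711363 and 714559, and the LD3 libraries 102019, 1298372 and 11145220. Between 9773 and 17340 loci had reads in a library. A count of 3 reads, the upper limit that a count of 0 allows, stood for 26.9, 28.5 and 1.85 reads per 1000000 (CPM) in LD0 A, B and C, for 19.8, 5.03 and 6.68 CPM in LD1, and for 23.4, 2.08 and 0.337 CPM in LD3. The RNA was amplified and reads carried no stated molecular identifiers, so these limits and the intervals given here cover counting error at most. They treat reads as independent, so they are too narrow where both reads of a fragment were counted. Libraries of the same time point correlated about as much as libraries of different ones, with median Pearson r across genes of 0.447 for 9 pairs and 0.451 for 27 pairs. Genes are not independent replicates in such a correlation.

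After 1 long day, the floral integrator SOC1 (AT2G45660), a MADS-box gene that promotes flowering, stood at 212 ± 116 CPM (SD, n = 3) against 5.84 ± 5.11 CPM in LD0. Its reads were 0, 1 and 13 in LD0 A, B and C and 50, 125 and 44 in LD1. The ratio of pooled reads was 24.1 (95% counting interval 14.1 to 44.9). SOC1 was higher in 3 of 3 letters. Cytosolic ribosomal protein genes rose as a list, and so did the list of floral promoters, while the list of heat shock genes fell. With an estimated correlation between members none of these 3 calls passed (adjusted p = 0.648 for each), and by fry their adjusted p were 0.108, 0.3004 and 0.314. Median differences within letters went the other way for floral promoters in C (−0.52) and for heat shock genes in B (+0.63).

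The floral promoter list had 24 members, of which 10 had enough reads for the test. Their median log2 fold change from LD0 to LD1 was +1.31, with 8 positive and 2 negative, and limma's camera gave an adjusted p of 0.0313 (adjusted p = 0.648 with an estimated correlation). SOC1 had a log2 fold change of +4.78 (SE 0.93). It was the 1 member with an adjusted p under the threshold when adjusted over the list alone (edgeR, 0.00281), and over all genes its adjusted p was 0.772. FD (AT4G35900), the bZIP partner of the florigen FT, was at 190 ± 137 CPM in LD0 and 360 ± 146 CPM in LD1, a log2 fold change of +1.24 (SE 0.69) that did not pass. FT (AT1G65480) itself had 4, 0 and 7 reads in LD0 and 232, 12 and 0 in LD1, a change of +5.24 (SE 2.29) carried mostly by LD1 A. The list contains FLOR1 (AT3G12145), the gene of a leucine-rich repeat protein. The series title names such a protein as a promoter of flowering found in these meristems, so this member is not independent evidence of the list's direction. The floral promoter call did not pass without 7 of the 9 libraries (all but LD1 C and LD3 A), with adjusted p from 0.0501 to 0.408, and among libraries A and B alone its adjusted p was 0.221. It did not pass with no filter (0.0550), a minimum count of 30 (0.311), 1 read column per library (0.0905) or thinned libraries (0.458) either. List tests with a library left out, with other filters or scalings, without the preparation term, with 1 read column or in thinned libraries were chosen after the data were seen, and those among A and B alone were planned.

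The ribosomal list had 187 tested members, 166 of them with a positive change from LD0 to LD1 and 21 with a negative one. Its median log2 fold change was +0.58 and its camera adjusted p 2.24e-06 (adjusted p = 0.648 with an estimated correlation). Among A and B libraries alone the adjusted p was 0.00525. Many ribosomal proteins have near-identical gene copies, and how reads that match several copies were counted is not given in the sources used here, so values of single copies are uncertain. The share of reads on the ribosomal list was 10.6%, 11.8% and 11.4% in LD0 and 18.8%, 11.04% and 20.5% in LD1, so LD1 B lay within 1 percentage point of the LD0 libraries. All 5 tested heat shock genes had negative values, with a median of −3.16 and a camera adjusted p of 0.00606 (adjusted p = 0.648 with an estimated correlation). None of the 5 passed when adjusted over the list alone. The heat shock call did not pass without any of 6 libraries (LD0 A, LD0 C, LD1 B, LD1 C, LD3 A and LD3 C), with adjusted p from 0.0501 to 0.515, and its adjusted p was 0.221 among A and B alone and 0.227 with no filter. The heat shock share of reads was 0.415%, 0.134% and 0.472% in LD0 and 0.0748%, 0.155% and 0.00126% in LD1. A list of seed storage and late-embryogenesis genes, assembled after the data were seen, took 9.32%, 2.48% and 9.10% of the reads of LD0 A, B and C and 1.18%, 4.97% and 0.118% of those of LD1.

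Of the other lists, 2 genes of gibberellin metabolism and signalling passed when adjusted over the list alone, each with an adjusted p of 0.0362 by edgeR. They were GA20OX2, an enzyme of gibberellin synthesis, at 1.44 ± 2.49 CPM in LD0 and 89.4 ± 124 CPM in LD1, and RGL1, a DELLA protein that represses gibberellin responses, with no reads in LD0 and 45.9 ± 42.0 CPM in LD1. The gibberellin list as a whole did not pass, and the lists that did not pass had camera adjusted p from 0.153 (cytokinin signalling) to 0.819 (circadian clock). No single gene passed over all 9300 tested genes by edgeR's quasi-likelihood test between LD1 and LD0. At an unadjusted p under 0.05 there were 592 genes, 305 higher and 287 lower in LD1, where 465 are expected on average by chance. Wrong splits of the same libraries gave up to 941 such genes, so this excess is not evidence of a change. DESeq2 called 10 genes higher and 22 lower, and limma-voom called 0. The smallest adjusted p was 0.126 for STP4 (AT3G19930), a monosaccharide transporter chosen after its values were seen. It had 5, 3 and 1679 reads in LD0 and 0, 0 and 1 in LD1, so LD0 C held nearly all of its reads.

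**Figure D1:**
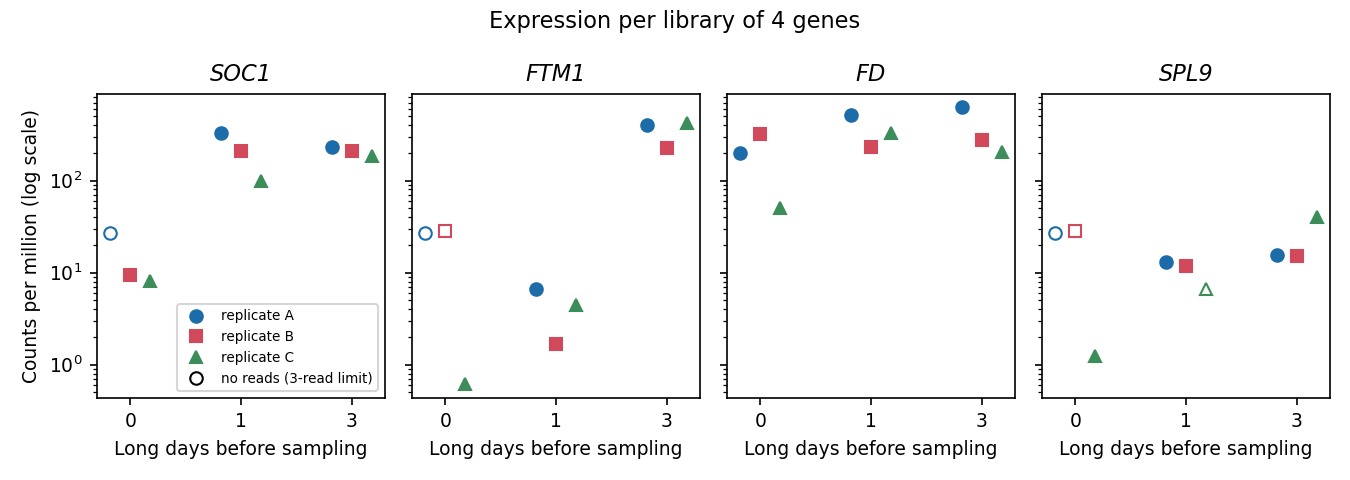
Normalised reads (CPM, log axis) of SOC1, FTM1, FD and SPL9 in each library against the number of long days. Each symbol is a library, and open symbols are libraries with no reads, drawn at the limit of 3 reads. SOC1 stood at 5.84 CPM in LD0 and 212 CPM in LD1 on average, and FTM1 rose from 0.205 CPM in LD0 to 350 CPM in LD3.

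After 3 long days, the strongest single change was that of FTM1 (AT1G43800), annotated as a member of the stearoyl-acyl carrier protein desaturase family. It had 0, 0 and 1 reads in LD0, 1, 1 and 2 in LD1 and 52, 327 and 3708 in LD3, and its mean level was 0.205 ± 0.356, 4.24 ± 2.46 and 350 ± 107 CPM (SD, n = 3). SOC1 was at 210 ± 23.9 CPM in LD3. Ribosomal protein genes and floral promoters rose as lists from LD0 to LD3, as did a list with 2 tested floral organ identity genes. Heat shock genes, genes of sugar starvation and trehalose metabolism, and genes of the cold, drought and abscisic acid response fell as lists. With an estimated correlation none of these 6 calls passed, with adjusted p = 0.385 as the smallest. By fry the ribosomal and floral organ lists passed (adjusted p 0.0256 for each), while floral promoters (0.134), heat shock (0.153), sugar starvation (0.153) and the cold and drought list (0.437) did not.

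FTM1 was the 1 gene called in the joint test of the 3 time points over 9300 genes, with an edgeR adjusted p of 0.0180, and 534 genes had an unadjusted p under 0.05. DESeq2 called 35 genes in the joint test and limma-voom 0. FTM1 was chosen after its values were seen. Its symbol refers to the floral transition at the meristem, so it is not independent of studies like this one. The ratio of pooled reads of FTM1 was 780 between LD3 and LD0 (95% counting interval 140 to 30800) and 126 between LD3 and LD1 (49.3 to 464). The fitted log2 fold change was +9.45 (SE 1.22) from LD0 to LD3, with an adjusted p of 0.0540 in the pairwise test, and FTM1 was higher in 3 of 3 letters. The pairwise change passed under 5 of 24 alternative settings, among them the fit with the replicate letters as a block. The joint call did not pass without any of LD0 A (adjusted p 0.0844), LD0 C (0.352), LD1 C (0.0654), LD3 A (0.245), LD3 B (0.154) or LD3 C (0.556). It was 0.837 among libraries A and B alone, 0.355 by limma-voom, 0.117 with 1 read column per library and 0.231 in thinned libraries, and over all alternatives it ran from 1.21e-09 to 0.837.

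The 10 tested floral promoters had a median log2 fold change of +1.33 from LD0 to LD3, with 8 positive and 2 negative, and a camera adjusted p of 0.0128 (adjusted p = 0.422 with an estimated correlation). SOC1 changed by +4.84 (SE 0.92) and passed when adjusted over the list alone (edgeR, 0.00233), while its adjusted p over all genes was 0.316. SPL9 (AT2G42200), an age-pathway transcription factor, had 0, 0 and 2 reads in LD0, 2, 7 and 0 in LD1 and 2, 22 and 353 in LD3, and its adjusted p over the list alone was 0.111. Its relative SPL15 (AT3G57920) was at 57.7 ± 21.95, 134 ± 21.6 and 293 ± 419 CPM at the 3 time points. LD3 A, B and C stood at 31.2, 72.0 and 776.5 CPM, so LD3 C carried the LD3 mean. FD changed by +1.11 (SE 0.67), FLOR1 by +0.84 (SE 0.68), FT by +0.75 and AGL24 (AT4G24540) by −0.08, none of which passed. The floral promoter call did not pass without LD0 C, LD1 B, LD1 C or LD3 C, with adjusted p from 0.0537 to 0.184, and its adjusted p was 0.0827 among A and B alone, 0.0823 with a minimum count of 30 and 0.0740 in thinned libraries.

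Several meristem identity genes had too few reads for the test. FUL (AT5G60910), a MADS-box gene of the transition, had 0, 0 and 2 reads in LD0, 0, 3 and 0 in LD1 and 3, 21 and 54 in LD3. Its ratio of pooled reads from LD0 to LD3 was 7.44 (95% counting interval 1.99 to 62.5), weighted to LD3 C. Its mean level was 0.411 ± 0.712 CPM in LD0 and 14.7 ± 8.66 CPM in LD3. In the authors' deposited table FUL had a log2 fold change of 3.84 between LD3 and LD0, with an unadjusted p of 0.0385. AP1 (AT1G69120), which specifies floral meristems, had 15 reads in LD1 B, 3 in LD3 B and 0 in the other 7 libraries. LFY (AT5G61850) had 0, 1 and 2 reads in LD0, 0 in each LD1 library and 0, 0 and 45 in LD3. SPL4 (AT1G53160) had reads in LD3 alone, 5, 7 and 2 of them. SPL3 (AT2G33810) had 1 read in LD0 C and 5 in LD3 C, and SPL5 (AT3G15270) had 1 in LD1 C and 10 in LD3 C. AGL42 (AT5G62165) had 24 reads in LD1 B and 0, 1 and 32 in LD3. The floral repressor FLC (AT5G10140) had 0, 4 and 9 reads in LD0, 0 in each LD1 library and 0, 5 and 6 in LD3. As depth differed, these reads do not give directions of change. Mean CPM in LD0 and LD3 were 3.58 and 1.69 for LFY, 0.205 and 0.187 for SPL3 and 14.5 and 1.38 for FLC. They were 0 and 0.693 for AP1, 0 and 14.7 for SPL4, 0 and 0.375 for SPL5 and 0 and 1.43 for AGL42.

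The list of floral organ identity genes had 2 tested members of 16, and both had positive changes from LD0 to LD3, with a camera adjusted p of 0.0193 (adjusted p = 0.385 with an estimated correlation). UFO, an F-box protein that acts with LFY, was at 10.1 ± 17.44 CPM in LD0 and 95.8 ± 133 CPM in LD3, a log2 fold change of +3.36 (SE 1.17) that passed when adjusted over the list alone (edgeR, 0.0286). MYB17 changed by +1.04 (SE 1.01) and did not pass. This call did not pass without any of 8 libraries (all but LD1 B), with adjusted p from 0.118 to 0.434, or with no filter (0.610) or no preparation term (0.119). The class genes of petals, stamens and carpels had too few reads to be tested.

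The median log2 fold change of the ribosomal list was +0.70 from LD0 to LD3, with 175 members positive and 12 negative and a camera adjusted p of 1.10e-05 (adjusted p = 0.391 with an estimated correlation). None of the members passed when adjusted over the list alone (edgeR). Among A and B libraries alone camera gave an adjusted p of 7.06e-10. The ribosomal share of reads was 19.6%, 20.3% and 22.8% in LD3 against 10.6%, 11.8% and 11.4% in LD0, means of 20.9% ± 1.70 and 11.3% ± 0.574 (SD, n = 3). An exact two-sided permutation test of this share gave p = 0.1, the smallest that 3 libraries against 3 allow. The scaling of libraries moved the median of all genes between LD3 and LD0 from +0.09 with TMM factors to −0.18 with RLE and +0.30 with upper-quartile factors. Relative to that median, the ribosomal list stood at +0.61, +0.60 and +0.61. The list of DNA replication and S phase genes had a median of +0.45, with 20 positive and 4 negative, and an adjusted p of 0.110 by camera and 0.0269 by fry, which tests whether the genes of a list change, on balance, in 1 direction and does not compare them with other genes.

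All 5 tested heat shock genes had negative fitted changes from LD0 to LD3, with a median log2 fold change of −4.43. Their camera adjusted p was 3.39e-05 (adjusted p = 0.385 with an estimated correlation). Median differences within letters were −5.27 in A, −0.30 in B and −7.11 in C, so B showed little fall. The C value was the same from LD0 to LD1. The prior count sets it where a gene has no reads in the later library, so its size is not a measured change. The cytosolic chaperone genes HSP17.6A, HSP101, HSP17.4 and HSP90.1 each had an adjusted p of 0.0246 by edgeR when adjusted over the list alone. HSP17.6A went from 1274 ± 999 CPM to 47.5 ± 29.1 CPM and HSP101 from 307 ± 169 CPM to 31.9 ± 37.8 CPM. The sugar starvation and trehalose list had 2 positive and 9 negative members, a median of −3.76 and a camera adjusted p of 0.000241 (adjusted p = 0.385 with an estimated correlation). The members that passed over the list alone were DRM2 (−6.42, SE 1.42, adjusted p 0.00843) and DRM1 (−6.11, SE 1.75, adjusted p 0.0257), known as dormancy-associated genes of buds. DRM1 was at 472 ± 143 CPM in LD0 and 9.29 ± 13.6 CPM in LD3. ASN1, an asparagine synthetase induced in darkness, changed by −6.24 (SE 2.32) and did not pass. Among A and B alone both the heat shock and the sugar starvation list had an adjusted p of 0.00882, and the latter had 0.0680 in thinned libraries.

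The cold, drought and abscisic acid list had 3 positive and 5 negative members, a median of −0.56 and a mean of −1.74, and a camera adjusted p of 0.0236 (adjusted p = 0.422 with an estimated correlation). It contained the dehydrins RAB18 (−4.95, SE 1.66) and LTI30 (−7.07, SE 2.45), each with an adjusted p of 0.0494 by edgeR over the list alone. Dehydrins accumulate in ripening seeds as well as under drought, and RAB18 is also on the seed list. The call did not pass without LD0 C (adjusted p 0.190) or with the seed and pollen list members removed (0.107) or with no filter (0.0964), and among A and B alone it had an adjusted p of 0.0304. The seed list share was 0.520%, 0.561% and 0.121% in LD3 A, B and C against 9.32%, 2.48% and 9.10% in LD0, and the heat shock share was 0.0118%, 0.0756% and 0.00417% against 0.415%, 0.134% and 0.472%. LD0 A, B and C and LD1 B had the 4 highest seed shares, the 4 highest heat shock shares and the 4 lowest ribosomal shares of the 9 libraries. The heat shock and ribosomal changes were therefore not separated from that of the seed transcripts.

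**Figure D2:**
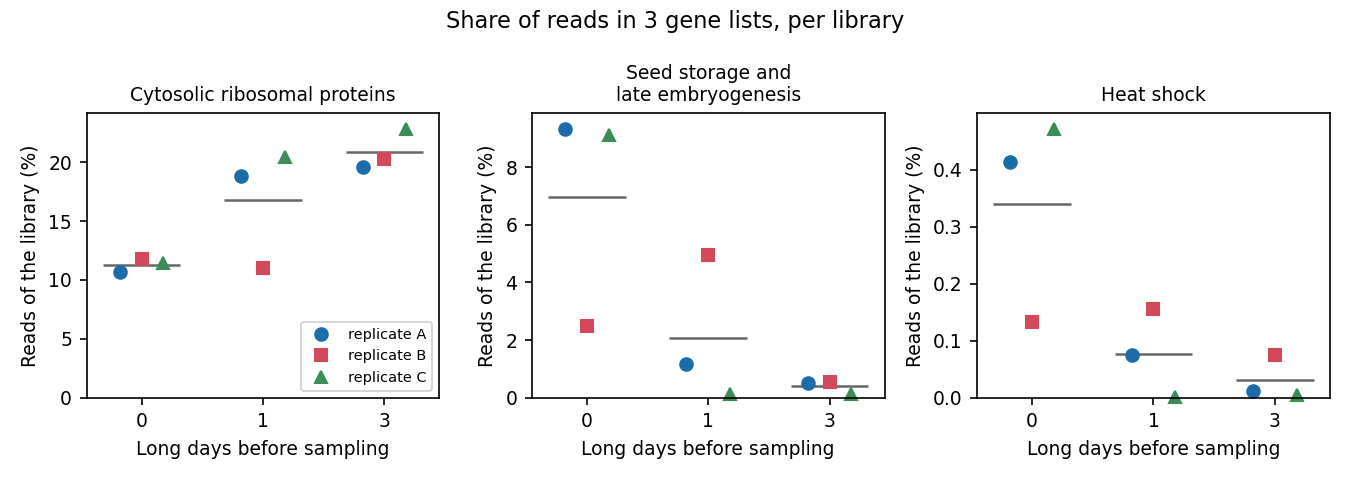
Percent of each library's reads on the ribosomal protein, seed and heat shock lists, against the number of long days. Each symbol is a library and each line the mean of a time point. The ribosomal share lay between 10.6% and 11.8% in LD0 and between 19.6% and 22.8% in LD3, and the seed share was 2.48% or more in LD0 and 0.561% or less in LD3.

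**Figure D3:**
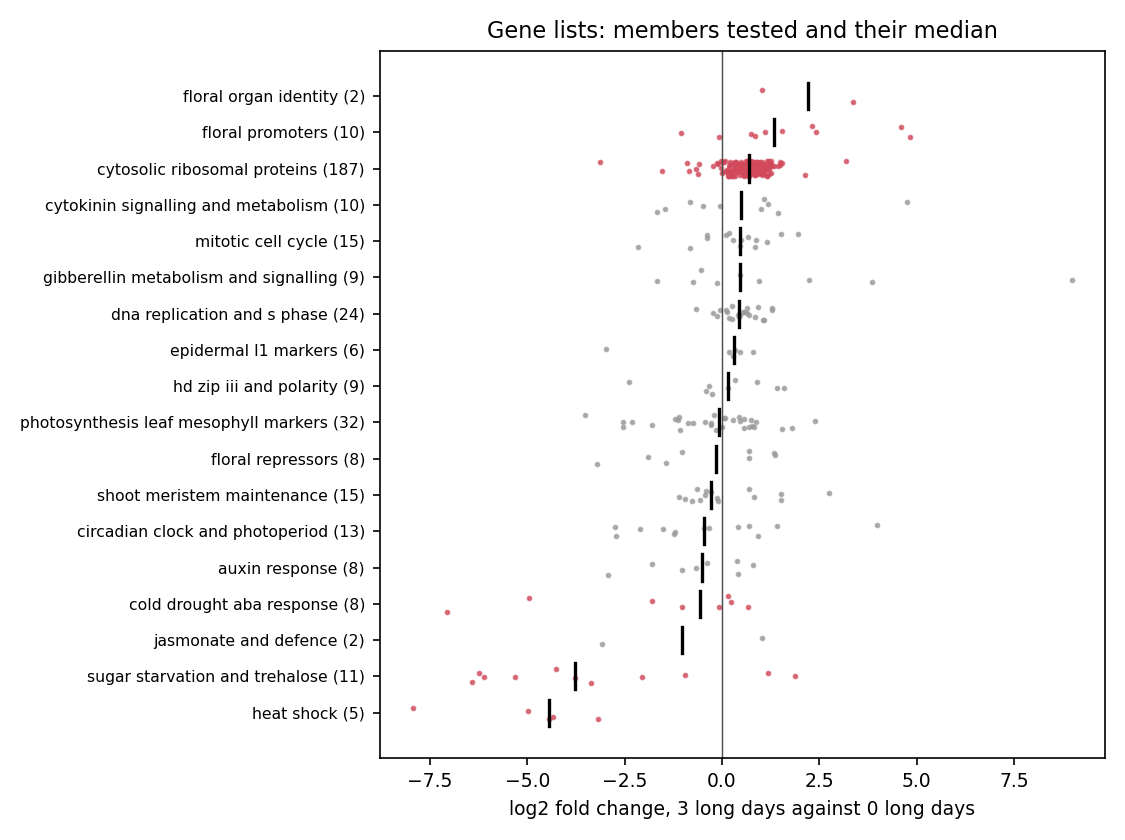
Log2 fold changes from LD0 to LD3 of the members of 18 gene lists fixed before the data were examined, with the median of each list and the number of tested members in brackets. Lists in red had a camera adjusted p under 0.05 with the preset correlation, and with an estimated correlation 0 lists passed.

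Lists of the meristem itself did not pass between LD3 and LD0. Meristem maintenance genes had a median log2 fold change of −0.27 and a camera adjusted p of 0.972. In this list STM (AT1G62360), which keeps meristem cells undifferentiated, was at 83.4 ± 92.4 CPM in LD0, 175 ± 123 in LD1 and 129 ± 59.9 in LD3, and the stem cell signal CLV3 (AT2G27250) was at 408 ± 151, 377 ± 159 and 261 ± 74.6 CPM. WUS (AT2G17950), the stem cell regulator upstream of CLV3, had 0, 1 and 19 reads in LD0, 0, 2 and 0 in LD1 and 0, 9 and 1 in LD3 and was not tested. Mitotic genes had a median of +0.47 (adjusted p 0.429), epidermal layer markers +0.32 (0.802) and polarity genes +0.15 (0.802, −0.13 with RLE factors). The mean log2 fold change had the other sign than the median for meristem maintenance (+0.13) and epidermal markers (−0.15), and camera gave the direction up for the former and down for polarity genes. Floral repressors had a median of −0.16 (adjusted p 0.954), +0.03 with upper-quartile factors, and in this group SVP (AT2G22540) changed by +0.70 and TFL1 (AT5G03840) by −1.89 (SE 1.99). TFL1 had 0, 1 and 272 reads in LD0 and 3, 14 and 78 in LD3, so its fall rests on LD0 C. It was higher in LD3 in 2 letters and lower in 1, and its change reached +2.27 under an alternative. Of the hormone and defence lists, auxin response had a median of −0.52 (0.802), cytokinin signalling +0.48 (0.429), gibberellin +0.46 (0.332) and jasmonate and defence −1.02 (0.802). The circadian list had a median of −0.46 (0.429), and in it GRP7, a clock-controlled RNA-binding protein, fell from 2813 ± 887 CPM to 1110 ± 597 CPM, a log2 change of −1.52 (SE 0.40) with an adjusted p of 0.0381 by edgeR over the list alone.

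Markers of tissues next to the meristem were also measured. Photosynthesis and leaf mesophyll genes had 32 tested members, a median of −0.07 (+0.22 with upper-quartile factors) and a camera adjusted p of 0.802 between LD3 and LD0. Of these, PSBP1 had a log2 change of +2.39 (SE 0.56) and an adjusted p of 0.0388 over the list alone by edgeR. Photosynthesis genes also have near-identical copies. Of 12 vascular markers 1 had enough reads for the test, with 638 reads on the list in all 9 libraries, and the trichome and stomata markers had 29 reads in all, so neither list was tested.

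No gene passed over all 9300 genes between LD3 and LD0 by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 250 genes higher and 487 lower in LD3, 737 in all against 465 expected on average by chance. Wrong splits of the same libraries gave up to 431 such genes, though the splits are too few for a share under 0.05. DESeq2 called 17 higher and 282 lower, edgeR's exact test without the preparation term 17 and 138, and limma-voom 0. The fit with the replicate letters as a block called 2 genes, FTM1 and AT1G68250. The genes with the next smallest p, chosen after their values were seen, were lower in LD3. The seed storage albumin gene SESA5 was at 7909 ± 4970 CPM in LD0 and 375 ± 306 CPM in LD3 (−4.74, SE 0.78), AT1G68250 was at 9683 ± 9028 and 69.2 ± 33.1 CPM, and ICL, the isocitrate lyase of the glyoxylate cycle, at 2647 ± 2044 and 86.8 ± 76.5 CPM. By this fit none of them passed over all genes, with an edgeR adjusted p of 0.205 for SESA5 and AT1G68250 and 0.316 for ICL. SESA5 passed over the seed list alone, but that list was written after SESA5 was known to be high.

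Between LD1 and LD3, the sugar starvation and trehalose list fell, and FTM1 had the smallest p. With an estimated correlation the list did not pass (adjusted p = 0.813), nor by fry (0.710), and its median differences within letters were −3.44 in A, −2.64 in B and +0.12 in C. The heat shock list had the same value in C, +0.12. The prior count sets such a value where genes have few or no reads, so C says little about the fall. The sugar starvation list had 1 positive and 10 negative members, a median log2 fold change of −3.08 and a camera adjusted p of 0.000274. DRM2 passed over the list alone, at 313 ± 354 CPM in LD1 and 6.87 ± 2.07 CPM in LD3 (−5.27, SE 1.305, adjusted p 0.0196 by edgeR). Among A and B alone the list had an adjusted p of 3.74e-05. FTM1 changed by +6.57 (SE 0.94) and had an adjusted p of 0.166, and SOC1 changed by +0.06 (SE 0.74). The lists that did not pass had camera adjusted p from 0.418 to 0.962, the ribosomal list among them with a median of +0.09, a direction that RLE factors turned to −0.12, and floral promoters with +0.11, turned to −0.08 and with a mean of −0.19. Camera's direction for the ribosomal list was down.

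No gene passed over all genes between LD3 and LD1 by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 146 genes higher and 233 lower in LD3, 379 in all against 465 expected on average by chance. Wrong splits of the same libraries gave up to 611 such genes. DESeq2 called 2 higher and 7 lower, the exact test 1 and 0, and limma-voom 0. Genes with small p, chosen after their values were seen, included NSP5, a nitrile-specifier protein gene, at 1833 ± 2071 CPM in LD1 and 73.0 ± 78.8 CPM in LD3, and the mitochondrial locus ATMG01390, at 7867 ± 10240 and 308 ± 93.4 CPM. ATMG01390 stood at 2167, 1745 and 19689 CPM in LD1 A, B and C, so LD1 C carried its LD1 mean.

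The authors' deposited tables gave an unadjusted p under 0.05 for 1460 loci between LD1 and LD0, 1673 between LD3 and LD0 and 1835 between LD3 and LD1. After Benjamini-Hochberg adjustment of those p-values, 0 loci passed in each of the 3 tables, with smallest adjusted p of 0.405, 0.174 and 0.367. Over the 9300 genes tested here, 278, 462 and 250 genes had an unadjusted p under 0.05 in both the authors' deposited tables and the edgeR fit, all with the same sign. Because the same reads lie behind both, this overlap is not independent evidence. For SOC1 the authors' deposited tables gave log2 fold changes of 4.998 between LD1 and LD0 and 5.06 between LD3 and LD0, and for FTM1 9.43 between LD3 and LD0.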

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

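The fits with 1 read column per library, with loci removed or with thinned libraries were chosen after the data were seen, as were the list tests under other scalings and filters, without the preparation term and with a library left out. Under 24 settings, 13 results (gene counts, list counts and overlaps with the authors' tables) gave 235 alternative values, of which 183 stayed within 1.5 times the reported count and 52 did not. Of values for single lists, named genes and the joint call of FTM1, 1640 stayed on their side of the threshold, 69 lost it, 56 gained it and 0 called values reversed. Named genes gave 1526 of these values, and no named gene passed in a reported pairwise test. All 69 losses therefore fell on list calls or the joint call of FTM1. The 1640 are mostly values that passed in neither fit, so they say little about the stability of calls. The sign of values that had not passed changed under some alternative for 15 of 69 results of named genes.

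Without a filter on low counts, edgeR called 21 genes higher and 86 lower in LD1 than LD0, 10 and 357 in LD3 than LD0, 10 and 176 in LD3 than LD1, and 433 in the joint test, where the reported counts were 0 and 1, and 1 list passed between LD1 and LD0. DESeq2 called 10 and 22, 17 and 282, 2 and 7, and 35 in the joint test. The exact test called 17 higher and 138 lower in LD3 than LD0 and 1 higher in LD3 than LD1. Under no filter, DESeq2 and the exact test alike, 101 genes were lower in LD3 than LD0, 11 of them in the seed or pollen lists. Upper-quartile factors called 1 gene higher in LD3 than LD0. The joint count was 2 with RLE factors and with a minimum count of 30, and 0 with limma-voom, with libraries A and B alone, with 1 read column per library and after thinning. The last 3 hold fewer samples or reads, and the cause of the other differences was not tested. The pairwise counts were 0 without the preparation term.

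With the replicate letters as a block, 1 gene was higher (FTM1, adjusted p 0.0337) and 1 lower (AT1G68250, 0.00481) in LD3 than LD0 and these 2 genes passed the joint test, and it changed no other count of calls by over 1.5 times. Same-lettered libraries deviated together in 8 of 9 pairs with r over 0.1 (0.0730 to 0.352), against −0.292 to 0.0402 for different letters, and 9 of 9 libraries correlated best with their own letter. This is a weak hint of pairing, which no label states. The C libraries share a preparation, which was not taken out of these deviations. Deviations from a mean of 3 libraries also sum to 0, which pushes values for different letters below 0.

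For lists, an estimated correlation passed 0, 0 and 0 lists and fry 0, 3 and 0 in place of 3, 6 and 1, and with libraries A and B alone 1 list passed between LD1 and LD0 and 4 between LD3 and LD1. With each library left out in turn, the pairwise gene counts ranged from 0 to 0, except genes lower in LD3 than LD0, which ranged from 0 to 1 (1 without LD0 B). The joint count ranged from 0 to 2 (2 without LD0 B, 0 without LD0 A, LD0 C, LD1 C, LD3 A, LD3 B or LD3 C). List counts ranged from 1 to 2 between LD1 and LD0 (1 without LD0 A, LD0 C, LD1 B or LD3 C), from 3 to 5 between LD3 and LD0 (3 without LD0 C) and from 1 to 4 between LD3 and LD1 (2 without LD1 A, 3 without LD1 B, 4 without LD1 C). Ribosomal calls, the heat shock call between LD3 and LD0 and both sugar starvation calls passed with each library left out, with highest adjusted p of 0.0221, 0.00339, 0.00613, 0.00739 and 0.0394. Depth limits genes with few reads: at 97153 reads a library gives 6594 to 10980 loci.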

Other observations

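The seed and pollen list tests, the 6 tests of their sources and of the ribosomal list other than splits, and the tests of LD1 C for counting noise and for a few genes with most reads were chosen after the result was seen, while the test of lost molecules and the splits were set before.

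Seed storage and late-embryogenesis genes were abundant in dissected meristems of plants in short days. Of 32 listed genes 27 were tested, and 27 of them were lower in LD3 than in LD0, with a median log2 fold change of −5.38 and a camera adjusted p of 1.24e-22 (adjusted p = 0.102 with an estimated correlation of 0.687 between members), and 24 had an edgeR adjusted p under 0.05 over the list alone. EM6, a late-embryogenesis protein, was at 17440 ± 14244 CPM in LD0 and 363 ± 199 CPM in LD3, and OLEO1, an oil body protein, at 2324 ± 1418 and 194 ± 184 CPM. From LD0 to LD1 the median was −3.22 (camera adjusted p 1.62e-13, adjusted p = 0.222 with an estimated correlation), and from LD1 to LD3 −2.38 (0.00701, adjusted p = 0.484 with an estimated correlation). Median differences of the seed list in A, B and C were −4.28, +1.28 and −9.62 from LD0 to LD1. They were −0.79, −3.37 and +0.74 from LD1 to LD3, so neither step fell in every letter. From LD0 to LD3 they were −3.98, −2.17 and −6.92. The 6 tested pollen genes had negative fitted changes from LD0 to LD3, with a median of −3.95 (camera adjusted p 0.0137, adjusted p = 0.305 with an estimated correlation), and 0 passed over the list alone. An exact two-sided permutation test of the pollen share gave p = 0.7. The pollen share was 0.000920%, 0.686% and 0.397% in LD0, 0.0450%, 1.01% and 0.0129% in LD1 and 0.00490%, 0.0847% and 0.0143% in LD3.

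Mitochondrial loci took 2.76% of the reads of LD1 C and 0.218% to 0.899% of those of the other libraries. STP2, a second sugar transporter gene, was at 198 ± 319 CPM in LD0, had no reads in LD1 and was at 8.06 ± 13.96 CPM in LD3. Its reads were 1, 2 and 919 in LD0 and 0, 0 and 215 in LD3, so the C libraries held nearly all of them. AT1G16770 was at 234 ± 114, 11.3 ± 9.53 and 4.73 ± 2.82 CPM, and AT1G17510 at 36.6 ± 47.3, 513 ± 697 and 152 ± 201 CPM. These genes were chosen after their values were seen.

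The high seed transcripts in LD0 may come from tissue carried into the dissection or from the meristem itself, and no test settled this. Fruit or flower RNA that brings seed and pollen transcripts together stays open: pollen reads per 1000 seed reads ran from 0.0987 in LD0 A, which had 1 pollen read, to 276 in LD0 B, and the counting limits differ by 460 times over all libraries but by 5.68 times over the 7 with 10 or more pollen reads, a restriction made after the value of 460 had been read as excluding this source. The restriction selects on the pollen reads under test and drops LD0 A, so it cannot speak for that library. LD0 A had the highest seed share (9.32%). Its upper limit was 0.550 pollen reads per 1000 seed reads, under the lower limit of 42.7 in LD0 C. For 1 seed source of fixed composition, the criterion was changed after its result was seen. It was set at first on LD0 C and LD1 B alone, where the spread of the gene ratios lay at the 97.9th percentile of matched random gene sets, which by that criterion argued against it. A single pair of libraries excludes little, so the criterion became a majority of the 36 pairs, 13 of which lay above the 95th percentile, and the question stays open, as do sources of differing composition and loss of these transcripts with time (exact two-sided permutation p = 0.1, the smallest possible).

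The ribosomal list rose from LD0 to LD3 by camera with the preset correlation and not with an estimated one (adjusted p = 0.391). To weigh dilution of meristem RNA by seed RNA in LD0, 69 genes of 5 lists were compared with the ribosomal list. The lists were meristem maintenance, polarity, epidermal markers, S phase and mitosis. Their median was +0.33 against +0.70, a difference of 0.37 (95% bootstrap interval 0.15 to 0.56). The 24 S phase and 15 mitotic genes had the highest list medians, +0.45 and +0.47. Meristem maintenance had −0.27, with 5 positive and 10 negative members, so the pooled median does not describe each list. The bootstrap resampled genes, which vary together, and holds no spread between libraries, so it cannot decide this. The libraries with the highest seed shares also had the lowest ribosomal shares, and dilution stays open as all or part of the rise. A difference in library preparation is argued against by the design, as each time point held the same mix of preparations. The list median also rose within each letter, by +0.61 in A, +0.75 in B and +0.73 in C. Among libraries A and B, which share a preparation, camera with the preset correlation gave an adjusted p of 7.06e-10. That value rests on few libraries and on the preset correlation, so its size does not measure the strength of the evidence. An increase with time in long days stays open, with an exact two-sided permutation p of 0.1 for the share of reads, the smallest possible.

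LD1 C had fewer loci than the other libraries at equal depth, 6594 at 97153 reads against 8973 to 10980. Counting noise is argued against, as 278 of 2646 genes with 50 or more expected reads had none, against 14 of 2625 in LD1 B at a like depth, and so is a few genes with most reads, since the 10 highest loci held 8.11% there and up to 10.5% in another library. Loss of molecules before sequencing is a candidate explanation: ribosomal protein genes spread 1.86 times as widely around their mean profile as in the median of the other libraries. LD3 C also lacked reads for 1598 of 13315 genes with 50 or more expected reads, so this is not a feature of LD1 C alone. Its ribosomal spread was wide too, 1.25 against 1.43 log2 units in LD1 C. Both are ready-to-run libraries and had the lowest seed shares, while the other ready-to-run library, LD0 C, lacked 175 of 6741. Lost molecules and a different composition were not told apart, and no biological explanation was tested.

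The 6 libraries of each pair of time points can be split in 10 ways, too few for a share under 0.05. The pairwise gene counts were 0 in the real split and at most 0 in the others, and 10 of 10 splits gave as many. The real split passed 3 lists between LD1 and LD0 (highest other 2, 1 of 10 as large), 6 between LD3 and LD0 (highest other 3, 1 of 10) and 1 between LD3 and LD1 (highest other 4, 8 of 10). The median of the seed list between LD3 and LD0 was −5.38, with 5.28 in size as the highest other. For the joint test 100 splits of the 9 libraries were drawn and 98 fitted, of which 8 called at least the 1 gene of the real split, so chance is not excluded. The highest other called 100 genes, and 5 splits called 44 to 100, each with LD1 B beside 2 LD0 libraries, which points to a structure of the samples that was not tested further. Another 5 splits with that arrangement called 0 to 6 genes.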
